A study of Mus musculus with 2 samples.

How the data were processed

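RNA-seq libraries were made from pericytes, the mural cells that wrap small blood vessels, isolated from mouse tumours on the C57BL/6 strain. Per the labels' protocols, the cells were purified by fluorescence-activated sorting, grown on gelatin, and used at passages 10 to 12. The RNA was extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit. There were 2 libraries, 1 from Cd248 null cells and 1 from Cd248 heterozygous cells. The markers used for sorting, the tumour model, the sex of the mice and the part of Cd248 removed in the null allele are not given in the sources used here.

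The authors deposited 1 table of FPKM (fragment counts divided by transcript length and by a library total), with 52636 Ensembl gene IDs and 1 column per library. Per the submitters' processing notes, the reads were handled with Bowtie2 (2.2.3) and the genome build mm8. The counting tool, the gene annotation and the total used as the denominator of FPKM are not given in the sources used here. No read counts were analysed. Because of the division by a library total, a few very abundant transcripts or a general shift in RNA content can move the values of other genes. The column names are codes that end in the letters N and P, and neither repeats a sample's title. N was read as null, and P was assigned to the heterozygote, before the Cd248 values were examined. Every direction given here rests on that reading, and the opposite reading would turn each of them around. The level of Cd248 itself serves as the check.

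Gene IDs were matched by ID to the GENCODE M21 annotation of GRCm38, which gave a symbol for 52403 IDs. The 233 unmatched IDs held 0.00523% of the summed FPKM in the null library and 0.00463% in the heterozygote library, and 8 of them reached an FPKM of 1. Of 52329 distinct symbols, 73 had more than 1 row, and the row with the highest mean FPKM stood for the symbol. The annotation build differs from mm8, so it was used for names, biotypes, transcript lengths and chromosome membership, and no coordinates are given.

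Depth was estimated from the low values. For genes with 1 annotated transcript and fewer than 10 reads, 98.6% of values in the null library and 98.5% in the heterozygote library were whole multiples of 1 read, within a tolerance of 0.02 reads. Between 10 and 1000 reads the shares for these genes were 80.3% and 94.2%, so the step size fits less well there, above all in the null library. The size of these steps gave normalizing totals of about 19787500 reads for the null library and 23982300 for the heterozygote library, a ratio of 1.21. For genes with several transcripts the length used by the authors could not be recovered, and 4.83% and 3.96% of values between 10 and 1000 reads came out whole. Counts were therefore not reconstructed for all genes and no count model was run. For Cd248 the null value was taken as 3 whole reads and the heterozygote value was rescaled to match. At these depths an FPKM of 1 on a transcript of 1 kb stands for 19.8 reads in the null library, with an exact 95% Poisson interval of 12.2 to 30.9, and for 24.0 reads in the heterozygote library, with an interval of 15.4 to 35.7. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

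With 1 library per genotype there is no measure of the spread between cultures or animals. No statistical test across genes was run, and no p-value or standard deviation is given. The measure was the log2 ratio of null to heterozygote after adding a pseudocount of 1 to each FPKM, which understates the difference of low genes. Genes with an FPKM of at least 1 in at least 1 library were compared, and a difference of at least 2-fold on this scale was counted. Ratios of FPKM without the pseudocount are given as folds only where both libraries reached an FPKM of 1, except for Cd248, whose fold is given with its counting interval. A gene with a value of 0 is described as listed at 0.

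Before the data were examined, 38 gene lists were fixed. They covered the markers of pericytes, fibroblasts, endothelial cells, myeloid cells, lymphocytes, epithelium, Schwann cells, adipocytes, skeletal muscle and bone, the Wnt, TGF-beta, Notch and growth factor pathways, angiogenic factors and inhibitors, the extracellular matrix, stress, immune and metabolic programmes, and control sets. For each list the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins (seed 7). A list with at least 4 expressed members was called apart when its median lay under percentile 2.5 or over percentile 97.5. This describes the 2 libraries and is not a test between genotypes. Lists share members, so they are not independent of each other.

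The rule for named genes was fixed at the same time. It took Cd248, the 12 genes with the highest and the 12 with the lowest log2 ratio among those with an FPKM of at least 5 in at least 1 library, and up to 3 members per direction of each list. Predicted genes without a descriptive name, small RNAs and pseudogenes recognised by name were left out of the ranking. Spp1, Axin2, Igfbp4, Lgals3bp, Pdgfrb, Cspg4, Rgs5 and Acta2 were named whatever their values. Some genes that the rule names are not reported here, and they remain in the counts and list medians. Lists of mesothelial markers, imprinted genes and genes that escape X inactivation were added after the data were seen, and their members are named in the closing section.

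The procedure was tested on simulated data for the comparison of null with heterozygote, over 12773 genes of which 200 were changed 4-fold. Among the 147 changed genes with a mean FPKM of at least 5, 100% passed the 2-fold mark in the right direction, as did 86.8% of the other changed genes. Of unchanged genes, 0.342% passed it. Without replicates, the spread between the simulated libraries had to be assumed. The shares of genes past the mark follow from that choice and are not error rates of the real comparison. All 20 simulated lists with shifted members were called apart, and so were 14 of 200 random lists. Shifts smaller than the simulated ones were not tried, so the sensitivity for the real lists is not known.

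The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a minimum FPKM of 5, scaling to a median log2 ratio of 0, to an equal column sum or to the upper quartile, summing the rows of a symbol, and a 4-fold mark. Scaling to an equal column sum multiplied the null column by 1.43 and the heterozygote column by 1.34. The pseudocount and the filter were left unchanged, so both weighed less in that setting, and 13459 genes were compared. Added after seeing the data were leaving out the X and Y chromosomes, leaving out chromosomes 1 and 11, and centring the log2 ratios by GC content and transcript length. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.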

Results

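The transcriptomes of tumour-derived mouse pericytes lacking Cd248 and of pericytes carrying 1 working copy were profiled by RNA-seq. Cd248 (endosialin) encodes a transmembrane C-type lectin of pericytes and stromal fibroblasts, and the study asked what it does in tumour pericytes, with Wnt signalling and the control of angiogenesis as its background. There was 1 library per genotype. Both came from sorted primary cells cultured to passages 10 to 12. The FPKM values deposited by the authors summed to 700322 in the null library and 744336 in the heterozygote library, and the steps between low values corresponded to 19.8 reads per kilobase at an FPKM of 1 in the null library and 24.0 in the heterozygote library. An FPKM of at least 1 was reached by 12012 gene IDs in the null library and 12010 in the heterozygote library. The 10 most abundant genes held 6.02% and 6.64% of the summed FPKM. No difference below has a replicate check, and each describes these 2 libraries. The assignment of the data columns to genotypes rests on the last letter of each column name, so all directions depend on it.

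Cd248 (ENSMUSG00000056481, on chromosome 19 in the GRCm38 annotation) was nearly undetected in the library read as null. Its FPKM was 0.0592 there and 20.98 in the heterozygote library. At the annotated transcript length these values correspond to 3.05 and 1311 reads, and the first is not a whole number within the tolerance used for depth. If the null value is taken as exactly 3 reads, the heterozygote value rescales to 1288 reads, and the exact 95% Poisson intervals are 0.0122 to 0.173 and 19.8 to 22.2. As an exception to the rule that folds need an FPKM of 1 in both libraries, made here for the targeted gene, the heterozygote value was 354-fold higher, with a counting interval from these reads of 121-fold to 1720-fold, and the null value was 0.282% of it. The targeted gene therefore goes with the reading of the column names. In the family of group 14 C-type lectins, Thbd, which encodes the anticoagulant receptor thrombomodulin, had FPKM values of 47.1 in the null library and 33.2 in the heterozygote library. The list had 2 expressed members and was not placed among random lists.

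The 2 libraries shared most of their expression profile, and a limited set of genes was close to absent from 1 of them. Of 12773 genes compared, 874 were at least 2-fold higher and 879 at least 2-fold lower in the null library, while 11020 (86.3%) lay within 2-fold. At least 4-fold differences were found for 180 genes higher and 284 lower, and at least 16-fold differences for 22 higher and 48 lower. Across genes, Pearson's r of the log2 values was 0.92 and Spearman's rho was 0.92, and genes are not independent replicates. The median log2 ratio was 0.03. The counts depended on the settings: with a pseudocount of 5 they were 400 higher and 369 lower.

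Among the genes higher in the null library, Cd53, a leukocyte tetraspanin, had the highest log2 ratio, 6.86, with FPKM values of 124 in the null and 0.0718 in the heterozygote library. Xist, the RNA that silences the second X chromosome in female cells, followed at 74.2 and 0.0133. Igf2, an imprinted fetal growth factor, stood at 41.2 in the null library and 0.104 in the heterozygote library. The acute-phase gene Saa3 (55.8 and 0.231) and the pentraxin Ptx3 (43.7 and 0.270) were also high in the null library alone, as were Sfrp1, a secreted Wnt antagonist (50.2 and 0.858), and Smoc1, which encodes a matricellular protein (27.8 and 0.0970). Other genes of this set were Kif1a (56.8 and 0.0674), Elfn1 (68.1 and 0.412), Syt13 (32.9 and 0.0998) and Ms4a4d (38.1 and 0.331).

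The genes with the lowest ratios were led by products of epithelia and mesothelium. The uroplakin Upk3b had an FPKM of 0.430 in the null library and 330.2 in the heterozygote library, and Upk1b had 0.314 and 118. The keratin Krt18 stood at 0.0361 and 196. Mesothelin (Msln) was 111-fold lower in the null library, at 2.10 against 234, and the retinaldehyde dehydrogenase Aldh1a1 was 173-fold lower, at 1.17 against 202. Wt1, a transcription factor of mesothelium and kidney, had 0.160 and 55.4. Esam, an adhesion molecule of endothelium and platelets, had 0.201 and 64.0, and the glutathione peroxidase Gpx3 had 0.0973 and 49.3. Tspan8, the imprinted gene Peg3 and the angiotensin receptor gene Agtr2 were listed at 0 in the null library, against 88.7, 52.1 and 45.4 in the heterozygote library. Rps4l stood at 0.0584 and 97.8. It is annotated as a processed pseudogene, and its value is uncertain because reads from ribosomal protein genes can be shared between near-identical copies.

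**Figure D1:**
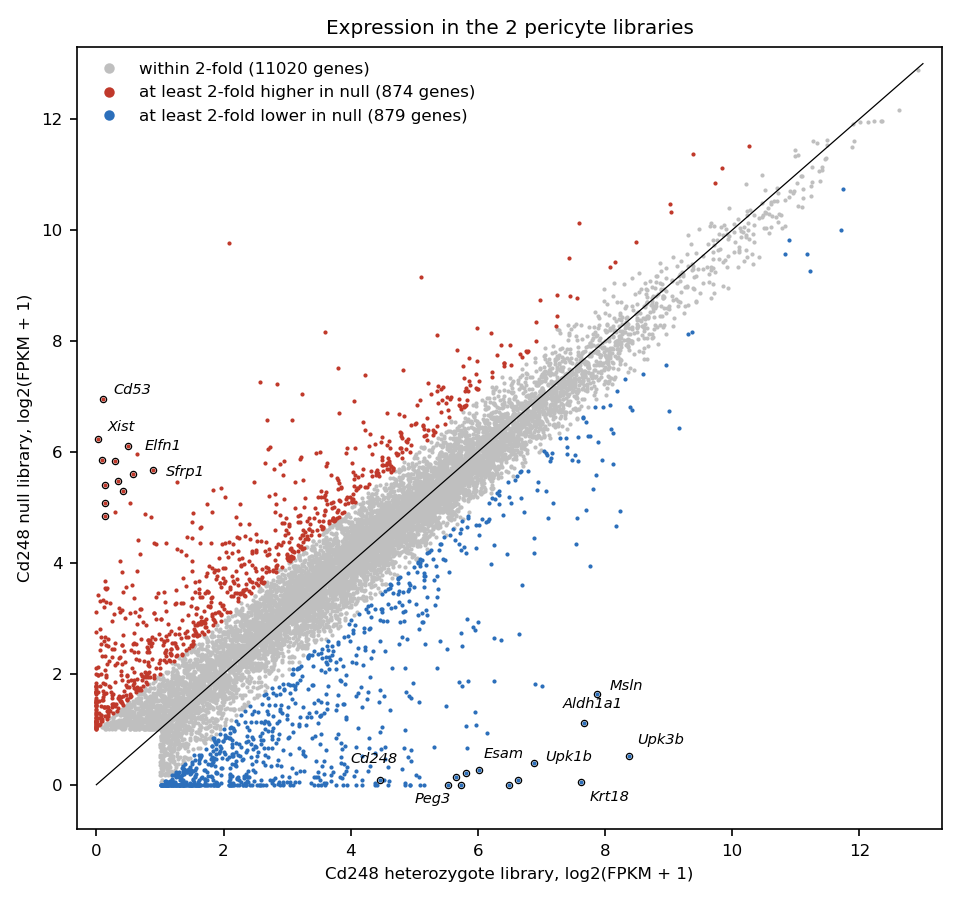
Expression of 12773 genes in the heterozygote library (horizontal axis) and the null library (vertical axis), both as log2 of FPKM plus 1; each point is 1 gene, the line marks equal values, and circles mark Cd248 and the 24 genes with the highest and lowest ratios. Most genes (11020) lie within 2-fold of the line, and Cd248 lies near 0 on the vertical axis.

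The genes tied in advance to Wnt signalling and angiogenesis did not move in 1 direction. Igfbp4, which encodes a binding protein for insulin-like growth factors and an inhibitor of Wnt signalling, was 6.23-fold higher in the null library, at an FPKM of 61.9 against 9.94. Lgals3bp, a secreted glycoprotein gene, was lower there, at 88.0 against 152, within the 2-fold mark. Spp1, which encodes osteopontin, stood at 316 in the null library and 186 in the heterozygote library. It was within the 2-fold mark. Axin2, a general readout of Wnt and beta-catenin signalling, had low values, 0.624 and 1.20.

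Of 18 expressed canonical Wnt target genes, 4 were at least 2-fold higher in the null library, 2 lower and 12 within 2-fold. The higher members included the matricellular gene Ccn5 (29.1 in the null library and 0.223 in the heterozygote library) and the Wnt antagonists Nkd2 (4.75 and 0.111) and Nkd1 (1.25, and listed at 0). The lower members were Rnf43, a ubiquitin ligase that removes Wnt receptors (0.0226 and 2.90), and the growth factor Bmp4 (4.32 and 12.2). The list median was -0.14, at percentile 19.8 of random lists, and the mean was 0.23, so median and mean differed in sign. With columns scaled to an equal sum the median was -0.05, with a minimum FPKM of 5 it was -0.06, and without chromosomes 1 and 11 it was 0.11. Among 29 expressed Wnt ligands, receptors and secreted regulators, 4 were higher and 8 lower. Sfrp1, the Wnt agonist gene Rspo3 (8.11 and 0.274) and the receptor gene Fzd1 (58.8 and 8.33) were higher in the null library, while Dkk3 was 56.3-fold lower (1.10 and 61.8) and Wnt9a (0.838 and 9.86) and Sfrp4 (0.126 and 2.90) were also lower. The median of this list was 0.04, at percentile 43.2, with a mean of -0.004. With a minimum FPKM of 5 it was 0.34 and lay at the upper mark for standing apart without passing it. It changed sign under upper quartile scaling (-0.01), with no filter on low values (-0.02), without chromosomes 1 and 11 (-0.01) and after centring by GC content and transcript length (-0.04).

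**Figure D2:**
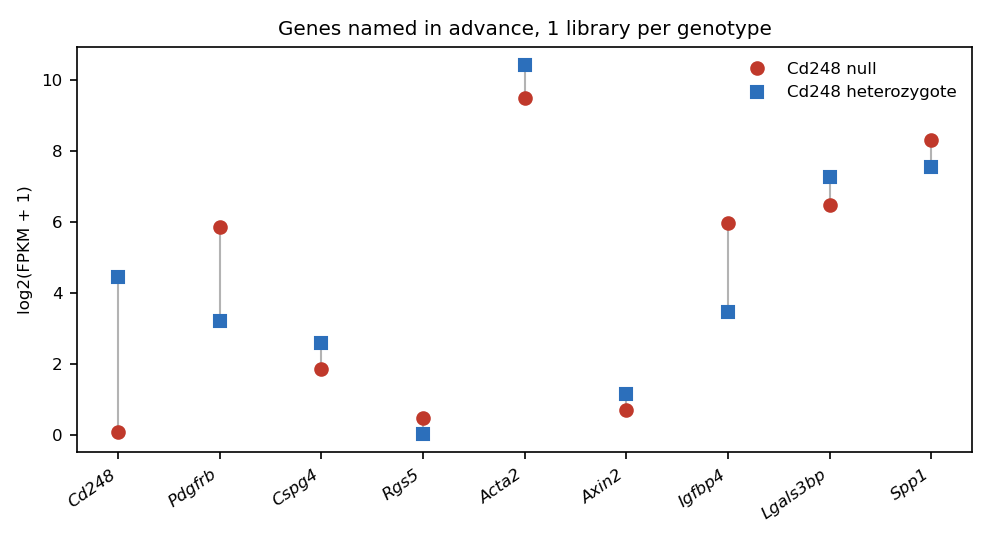
Levels of Cd248 and 8 genes named in advance, as log2 of FPKM plus 1, with 1 circle for the null library and 1 square for the heterozygote library per gene; there are no error bars because each genotype has 1 library. Cd248 has the widest gap, Pdgfrb and Igfbp4 are higher in the null library, and Acta2 is lower.

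The pericyte markers were expressed unevenly in both libraries. Pdgfrb, the platelet-derived growth factor receptor of mural cells, was 6.95-fold higher in the null library (57.3 against 8.25), and the transcription factor gene Foxc1 was 3.34-fold higher (8.24 against 2.47). The smooth muscle actin gene Acta2 stood at 726 in the null library and 1367 in the heterozygote library. Cspg4, which encodes the NG2 proteoglycan, stood at 2.59 and 5.02. Rgs5 was below an FPKM of 1 in both, at 0.377 and 0.0173. Of the 22 genes on the list, only 11 reached an FPKM of 1 in at least 1 library. Of these 11, 2 were at least 2-fold higher, none lower and 9 within 2-fold. The median was 0.33, at percentile 91.3. It was 0.08 with a minimum FPKM of 5 and also without chromosomes 1 and 11, at percentiles 56.0 and 56.4, and -0.02 with no filter on low values. After centring by GC content and transcript length it was 0.45, at percentile 97.4. Fibroblast markers split evenly, with 5 of 15 higher, 5 lower and a median of 0.14 at percentile 82.0. The elastic fibre gene Mfap5 (166 and 17.8) and the surface antigen gene Ly6a (274 and 39.8) were higher in the null library, and Cd34 (0.02305 and 11.3) and the proteoglycan gene Dcn (20.8 and 117) were lower. With a minimum FPKM of 5, the fibroblast median was 0.62, at percentile 99.9, and with no filter it was 0.08.

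Markers of other cell types differed between the libraries too, and this holds beside every gene group described here. Of 5 expressed epithelial markers, 4 were lower in the null library and Muc1 was higher (2.26 and 0.544). The median was -3.23, under every one of the random lists. The lower members included the keratins Krt18, Krt19 (14.4 and 217) and Krt7 (0.555 and 13.6). With no filter on low values the median was -0.40, and the list still stood apart. Of 4 expressed Schwann cell markers, 3 were lower, among them the myelin gene Mbp (1.65 and 17.1) and the axon growth gene Gap43 (1.90 and 18.2), and the median was -2.02 at percentile 0.02. With no filter it was -0.04, at percentile 12.0. Of 5 expressed endothelial markers, Esam and Flt4, the receptor of lymphatic endothelium (1.55 and 23.5), were lower and 3 lay within 2-fold. Their median was -0.64, at percentile 3.89, and the list came to stand apart with a pseudocount of 0.1 (-1.33), with no filter (-0.13) and with columns scaled to an equal sum (-0.72). It was -0.12, at percentile 31.0, without chromosomes 1 and 11, and -0.20 with a pseudocount of 5. Scaling to an equal sum also lessened the weight of the pseudocount and the filter, so that call cannot be laid to scaling alone. Of 6 expressed myeloid markers, Lyz2 (4.26 and 0.507) and Csf1r (2.10 and 0.195) were higher in the null library. Their median was 0.36, at percentile 82.6, it was -0.01 with no filter, and without chromosomes 1 and 11 it was 0.94, at percentile 98.2. No lymphocyte marker was expressed.

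Genes of 3 other mesenchymal lineages were mostly below the expression filter. The adipocyte list had 3, of which the lipase gene Lpl (0.572 and 55.7) and the regulator Pparg (0.952 and 5.82) were lower in the null library and Cebpa was higher (2.28 and 0.592). The skeletal muscle list had 2, of which Acta1 was lower (0.490 and 19.9) and Tnnt3 was within 2-fold (4.95 and 2.85). Neither was placed among random lists. The bone and cartilage list had 5, of which the transcription factor gene Sox9 was higher (10.3 and 4.30) and Ogn, which encodes osteoglycin, was lower (0.808 and 7.20). Its median was 0.60, at percentile 98.5, but its mean was -0.05, and the list no longer stood apart with no filter (0.02), with a minimum FPKM of 5 (percentile 97.4) or after centring by GC content and transcript length (0.48, at percentile 96.4).

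Genes for angiogenic factors were shifted upward in the null library. Of 26 expressed members, 9 were at least 2-fold higher and 5 lower, with a median of 0.69 that lay above every random list. The mean was smaller, at 0.28, and 17 members had log2 ratios above 0 and 9 below. With a pseudocount of 5 the median was 0.37. The chemokine gene Cxcl12 was 17.0-fold higher, at 567 against 33.3. Il6 (8.64 and 1.504) and Cxcl1 (3.97 and 0.0591) were also higher. Ptn, which encodes pleiotrophin (0.291 and 13.95), and Pdgfc (2.08 and 12.9) were lower. Among 15 expressed angiogenesis inhibitors, 4 were higher, including the protease inhibitor gene Timp3 (205 and 57.0), the thrombospondin gene Thbs2 (17.8 and 4.67) and Serpinf1 (642 and 270.2), and 3 were lower, namely Col4a3 (0.122 and 4.01), Cxcl10 (1.13 and 7.44) and Sfrp4. The median was -0.20, at percentile 10.4. It was -0.09 with a minimum FPKM of 5 and -0.12 with a pseudocount of 5. Without chromosomes 1 and 11 it was -0.45, at percentile 0.32.

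Extracellular matrix genes were also shifted upward in the null library. Of 23 expressed matrix glycoproteins and proteoglycans, 8 were at least 2-fold higher and none lower. The laminin gene Lama4 was 15.4-fold higher (28.8 against 1.87), the basement membrane gene Nid2 10.3-fold (54.6 against 5.28) and the tenascin gene Tnc 7.10-fold (47.1 against 6.63). The median was 0.54, above every random list, and 0.19 with no filter on low values. Of 30 expressed matrix proteases and crosslinkers, 6 were higher and none lower, with a median of 0.45 above every random list. Mmp19 (44.0 and 8.54), Timp3 and the gelatinase gene Mmp2 (140 and 42.0) led that list. Of 18 expressed collagens, 5 were higher and 1 lower, with a median of 0.30 at percentile 99.5. Col8a1 (35.4 and 10.6) and Col3a1 (435 and 187) were higher, and the basement membrane collagen gene Col4a1 was lower (157 and 318), just past the 2-fold mark. The collagen list no longer stood apart without chromosomes 1 and 11 (0.06), with no filter (0.15), with a minimum FPKM of 5 (0.19) or after centring by GC content and transcript length (0.17).

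The list of unfolded protein and amino acid stress genes had the highest median of all lists tested, 1.27. Of its 20 members, 12 were at least 2-fold higher in the null library, none lower and 8 within 2-fold, and the median lay above every random list. The members with the highest ratios work in the endoplasmic reticulum. Creld2 was 4.56-fold higher (227 against 49.8), the disulphide isomerase gene Pdia4 4.19-fold (717 against 171) and Sdf2l1 4.17-fold (151 against 36.2). The members with the lowest ratios were within 2-fold: the glutathione-degrading enzyme gene Chac1 (10.8 and 15.5), the serine synthesis gene Phgdh (430 and 552) and Sesn2 (15.6 in both). Cholesterol synthesis genes had a median of 0.71, above every random list, with 4 of 19 members at least 2-fold higher, none lower and 18 above 0. Sqle, which encodes squalene epoxidase (96.8 and 35.9), Fdps (6.45 and 2.06) and Cyp51 (185 and 83.7) led them. Of 23 expressed hypoxia response genes, 6 were higher, none lower, and the median of 0.46 lay above every random list. The pyruvate dehydrogenase kinase gene Pdk1 (35.3 and 10.2), the mitophagy receptor gene Bnip3 (49.1 and 15.4) and Egln3 (17.5 and 8.004) were higher, while the lactate dehydrogenase gene Ldha stood at 1575 and 2430.

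**Figure D3:**
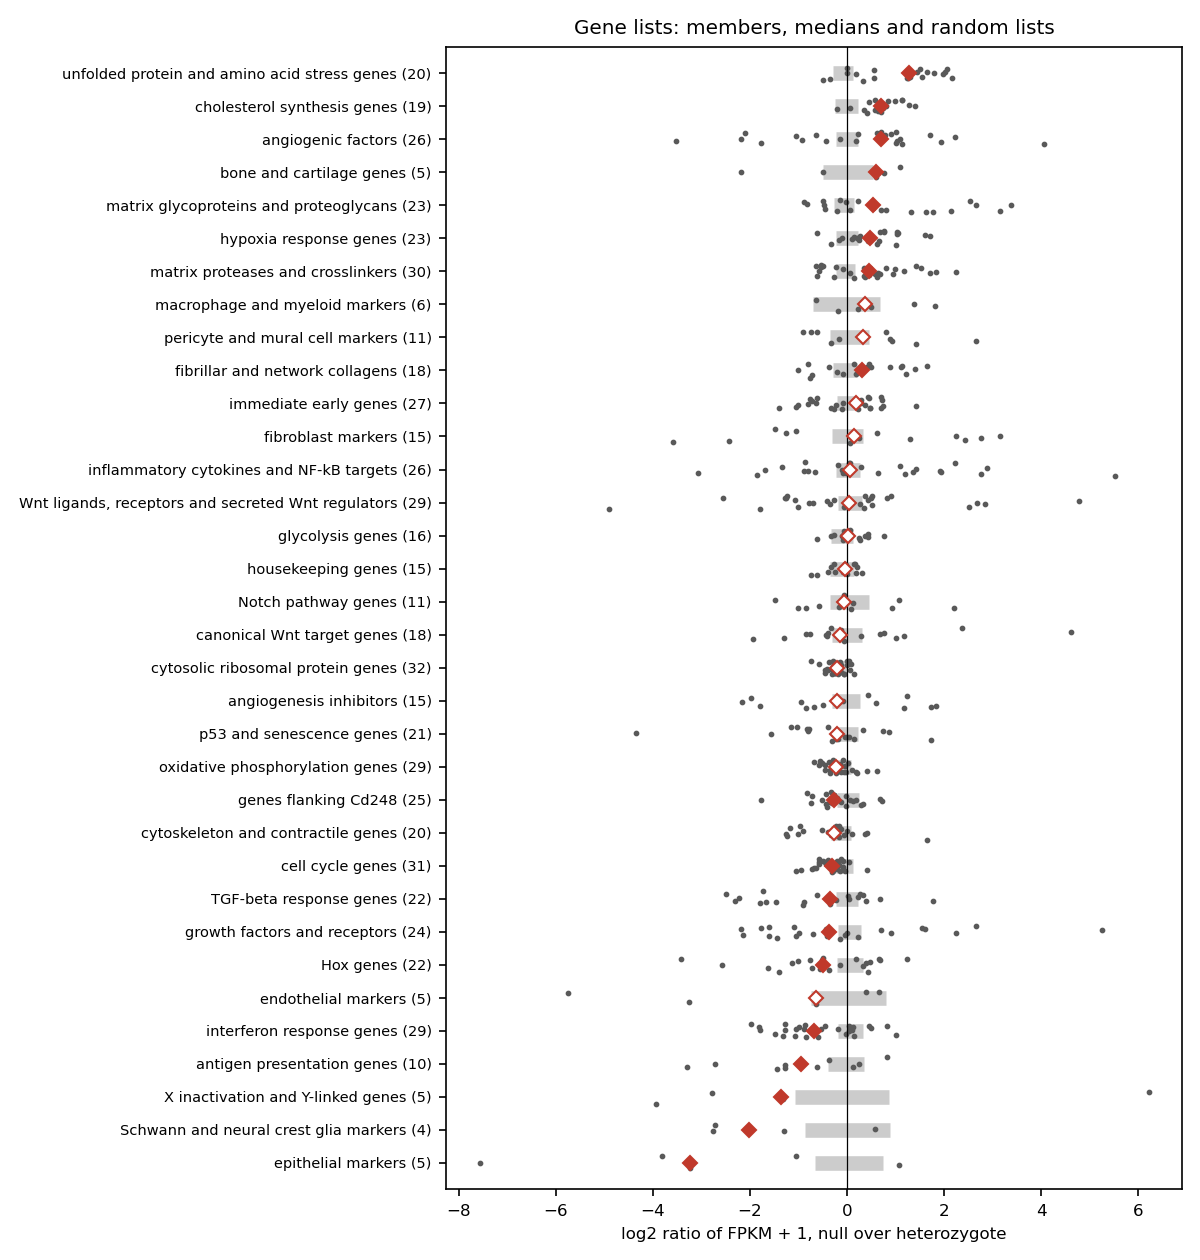
Log2 ratios of FPKM plus 1, null over heterozygote, for the 34 gene lists with at least 4 expressed members (number of expressed members in brackets): grey dots are single genes, diamonds are list medians, filled where the list stood apart, and grey bars span the central 95% of the medians of 10000 random lists. The stress list has the highest median (1.27) and the epithelial list the lowest (-3.23).

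Interferon response and antigen presentation genes were shifted downward in the null library. Of 29 expressed interferon response genes, 9 were at least 2-fold lower and 1 higher, with a median of -0.68 under every random list. With a pseudocount of 5 it was -0.40. The chemokine gene Cxcl10, the antiviral gene Oas1a (0.751 and 5.13) and the transcription factor gene Irf7 (4.37 and 17.7) were lower, and the GTPase gene Iigp1 was higher (2.27 and 0.619). Of 10 expressed antigen presentation genes, 5 were lower and none higher, with a median of -0.95 under every random list. The class I genes H2-K1 (29.6 and 300.3) and H2-D1 (85.4 and 570.4) were 10.2-fold and 6.68-fold lower, and the peptide-loading gene Tapbp was 2.72-fold lower (77.5 and 211). H2-T23 stood at 27.2 and 14.9. The class I genes are similar in sequence, so the division of reads among them is uncertain. The median was -0.52 with a pseudocount of 5 and -0.31 with no filter. Inflammatory cytokines and NF-kB targets went both ways, with 10 of 26 higher and 4 lower and a median of 0.06 at percentile 61.0, which ranged from 0.003 under upper quartile scaling to 0.14 with columns scaled to an equal sum. Saa3, the chemokine gene Ccl7 (103 and 13.1) and Il1rn (7.91 and 0.316) were higher, and Csf3 (0.0358 and 7.70), Il33 (0.655 and 5.02) and Ccl20 (listed at 0, and 2.22) were lower.

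The list of TGF-beta response genes, which also holds ligand and receptor genes, was shifted downward in the null library. Of 22 expressed members, 7 were at least 2-fold lower, 1 higher and 14 within 2-fold, with a median of -0.35 at percentile 0.06. TGF-beta signalling itself was not measured, and the median of this mixed list is not a readout of it. The ligand gene Tgfb2 (0.470 and 7.25), the inhibitor of differentiation gene Id1 (27.0 and 137) and Ltbp2, which encodes a latent TGF-beta binding protein (14.7 and 72.6), were lower. Tgfbi was higher (17.6 and 4.46). Of 24 growth factor and receptor genes, most of the PDGF, FGF and EGF families and the others Igf1, Igf2, Igf1r, Hgf, Met and Axl, 8 were lower and 5 higher, with a median of -0.38 at percentile 0.04 and a mean of -0.03. The ligand genes Pdgfc, Tgfa (0.921 and 7.54) and Pdgfb (0.294 and 3.40) were lower, and Igf2, Pdgfrb and Igf1 (21.1 and 3.63) were higher. With a minimum FPKM of 5 this list no longer stood apart (-0.15, at percentile 10.1). Of 22 expressed Hox genes, which set position along the body axis, 6 were lower and 1 higher. Their median was -0.51, under every random list, and it was -0.26 with a pseudocount of 5 and -0.33 with no filter. Hoxa10 (0.598 and 15.998), Hoxd8 (listed at 0, and 4.95) and Hoxa9 (1.45 and 6.56) were lower, and Hoxa6 was higher (5.32 and 1.67). Notch pathway genes did not stand apart, with 2 of 11 higher, 2 lower, a mean of 0.02 and a median of -0.06 at percentile 28.2, which ranged from -0.18 after centring by GC content and transcript length to 0.09 with a minimum FPKM of 5. Dtx4 was higher (19.3 and 3.41) and Lfng lower (8.25 and 24.8). Immediate early genes had 1 of 27 higher and 3 lower. Egr2 was higher (5.59 and 1.47) and Ccn1 lower (188 and 496). Their median was 0.18, at percentile 96.5, and their mean was -0.02, of opposite sign. Without chromosomes 1 and 11 the median was 0.07, at percentile 79.5, with a pseudocount of 5 it was 0.10, and the list came to stand apart with a pseudocount of 0.1 (0.21), with a minimum FPKM of 5 (0.25) and after centring by GC content and transcript length (0.28).

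Cell cycle genes differed little singly but in the same direction. Of 31 members, 29 had log2 ratios below 0, and 1, the survivin gene Birc5 (37.3 and 77.8), was at least 2-fold lower in the null library. The median was -0.31, at percentile 0.12. Most ribosomal protein genes (26 of 32) and oxidative phosphorylation genes (23 of 29) also lay below 0, and neither list stood apart. The count of signs alone therefore says little, and members of such a list can vary together. Rrm2, a subunit of ribonucleotide reductase, stood at 95.8 and 187. Of 21 p53 and senescence genes, 4 were lower and 1 higher, with a median of -0.21 at percentile 5.34, which was -0.06 after centring by GC content and transcript length and -0.13 with columns scaled to an equal sum. The apoptosis gene Perp (0.0259 and 19.8) and the p53 antagonist gene Mdm2 (111 and 249) were lower, and Gdf15 was higher (10.1 and 2.37). Of 20 expressed cytoskeletal and contractile genes, 4 were lower and 1 higher, with a median of -0.28 at percentile 6.91. The myosin light chain genes Myl6 (760 and 1828) and Myl9 (114 and 270.2) were lower, and the enteric actin gene Actg2 was higher (199 and 62.7). Reads of actin genes can be shared between paralogs.

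The lists of glycolysis, ribosomal protein, oxidative phosphorylation and housekeeping genes did not stand apart, and none of their members passed the 2-fold mark. Glycolysis genes had a median of 0.03 at percentile 89.7, which ranged from -0.03 under upper quartile scaling to 0.15 after centring by GC content and transcript length. Cytosolic ribosomal protein genes had a median of -0.20 at percentile 32.1, and oxidative phosphorylation genes a median of -0.24 at percentile 6.62. After centring by GC content and transcript length these were -0.04 and -0.11, and with columns scaled to an equal sum -0.12 and -0.15. The housekeeping genes had a median of -0.04 at percentile 73.6, which ranged from -0.11 after that centring to 0.05 with columns scaled to an equal sum. Peptidylprolyl isomerase A (Ppia) had the lowest ratio among the housekeeping genes, at 1049 and 1768.

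The libraries also differed in sex-linked transcripts. Xist was high in the null library, while the Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were listed at 0 there and had FPKM values of 14.3, 5.91, 1.56 and 1.503 in the heterozygote library. This is the pattern of female cells in the null library and male cells in the heterozygote library, although the sources do not give the sex. The median of the 5 expressed genes was -1.36, at percentile 0.54, and the list holds genes of opposite expected direction. With pseudocounts of 0.1 and 5 it was -4.05 and -0.39. Leaving out the X and Y chromosomes gave 860 genes higher and 834 lower. Of 25 expressed genes flanking Cd248, 24 lay within 2-fold and Tmem151a was 3.48-fold lower in the null library (38.2 and 133). The median of this list was -0.26, at percentile 0.90, and after centring by GC content and transcript length it was -0.15, at percentile 5.67. In all, 18 of the 34 lists tested stood apart, 8 above and 10 below. The nominal rate of the percentile marks is 1.7 of 34, and on simulated data for this comparison 14 of 200 random lists stood apart. Both rates rest on genes drawn independently of each other. Members of a real list can vary together between 2 cultures, so neither rate measures how often such lists stand apart without a genotype effect.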

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

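No paired analysis was possible because there was 1 library per genotype. No called value changed sign under any setting. For single genes most settings could not have reversed a call, since a pseudocount or a filter keeps the sign of a ratio. Scaling to an equal sum, the largest of the scalings, moved the ratios by a median of 0.087 on the log2 scale, far short of the 2-fold mark. The settings that left out chromosomes or centred by GC content and transcript length were chosen after seeing the data. Against 874 genes higher and 879 lower, a pseudocount of 5 gave 400 and 369, a minimum FPKM of 5 gave 622 and 523, and a 4-fold mark gave 180 and 284. Each of these can only remove genes here, and the genes they left were all among those counted before. The other settings kept both counts within 1.5 times: a pseudocount of 0.1 gave 1306 and 1090, scaling to an equal sum 1195 and 911, to the upper quartile 815 and 923, to a median ratio of 0 877 and 875, centring by GC content and transcript length 903 and 838, leaving out chromosomes X and Y 860 and 834, and leaving out chromosomes 1 and 11 729 and 733. Scaling to an equal sum raised both columns against a fixed pseudocount and filter, so its counts and list calls do not show scaling alone. Cd248 remained at least 2-fold lower in each setting run for it, as did the 24 genes with the highest and lowest ratios in their own directions. Between 14 and 20 lists stood apart over 11 other settings, and 13 did so in each setting that could test them. The lists that lost their call were collagens with no filter (0.15), a minimum FPKM of 5 (0.19), without chromosomes 1 and 11 (0.056) and after GC and length centring (0.17); bone and cartilage with no filter (0.015), a minimum FPKM of 5 (0.60, at percentile 97.4) and GC and length centring (0.48); Schwann markers with no filter (-0.044); growth factors and receptors with a minimum FPKM of 5 (-0.15); and the genes flanking Cd248 after GC and length centring (-0.15). The lists that gained one were endothelial markers with a pseudocount of 0.1 (-1.33), no filter (-0.13) and an equal sum (-0.72), immediate early genes with a pseudocount of 0.1 (0.21), a minimum FPKM of 5 (0.25) and GC and length centring (0.28), fibroblast markers with a minimum FPKM of 5 (0.62), and, without chromosomes 1 and 11, angiogenesis inhibitors (-0.45) and myeloid markers (0.94). For these lists the cause was not tested. Lists left with fewer than 4 members under a setting gave no value there. For 215 named genes, 1439 values over the settings stayed on their side of the 2-fold mark, 47 fell inside it and 11 passed it, and 8 values near 0 changed sign. Depth limits genes near an FPKM of 1 on short transcripts, where the 95% counting interval of a single library spans more than 2-fold.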

Other observations

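The tests of mixed cells, and the lists of mesothelial, imprinted and X-escape genes, were chosen only after the results were seen; the tests on chromosomes and the centring of the stress list were set before their results were seen. Mesothelial genes had the lowest median log2 ratio of the lists examined, -4.93, under every one of 10000 random lists. Several members had already been seen among the genes with the lowest ratios when the list was made, so this rank is no independent result. Of 13 expressed members, 12 were at least 2-fold lower in the null library. Besides Upk3b, Upk1b, Msln, Wt1 and Krt18, the members Lrrn4 and Gpm6a were listed at 0 in the null library, against FPKM values of 29.5 and 29.5 in the heterozygote library. Bnc1 was the exception, at 2.93 in the null library and 0.727 in the heterozygote library. The list shares the keratins Krt18, Krt19 and Krt7 with the epithelial list. Krt8, the usual partner of Krt18, stood at 0 and 0.531, beside 196 for Krt18 in the heterozygote library, and was chosen for mention after its value was seen.

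Imprinted genes, which are expressed from 1 parental copy, differed in both directions. Of 19 expressed members, 6 were at least 2-fold lower and 3 higher in the null library, and the median was -0.31, at percentile 0.65. Peg3 and Igf2 had already been seen among the genes with the most extreme ratios, so this percentile is no independent result either. Peg3 and its neighbour Usp29 were both listed at 0 in the null library, against 52.1 and 3.29. Dlk1 was lower in the null library (0.251 and 11.9), while Rian and Meg3, RNAs of the same imprinted cluster made from the other parental copy, were higher (32.2 and 3.81, and 14.1 and 3.09). Igf2 was higher, as described above, and Grb10 (29.8 and 207) and Ndn (5.64 and 52.3) were lower. No explanation of the imprinted genes was tested. Of 7 genes that escape X inactivation, all had ratios above 0 and none passed the 2-fold mark, with a median of 0.50 at percentile 97.4, beside Xist in the null library and Y-linked RNA in the heterozygote library. The sex of the cells, as read from these transcripts, thus differs together with genotype and culture between the 2 libraries.

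Among genes with an FPKM of at least 5, the 560 of chromosome 1 were shifted upward in the null library by a median of 0.46 on the log2 scale against the other autosomes and the 844 of chromosome 11 by -0.33, while the 17 other autosomes lay between -0.18 and 0.21. After centring by GC content and transcript length the shifts were 0.416 and -0.301, which argues against such bias as the whole cause. The shifts were not due to a few genes or 1 region, since 100% of the 28 blocks of 20 neighbouring genes on chromosome 1 and 100% of the 42 blocks on chromosome 11 lay on the side of the shift, although on other autosomes this share also ranged from 42.9% to 100%, with a median of 81.5%. The quartile nearer to 0 was shifted by 0.463 on chromosome 1 and by -0.381 on chromosome 11, as a hypothesis of extra copies of whole chromosomes in part of the cells (chromosome 1 in the null culture, chromosome 11 in the heterozygote culture) predicts. Both chromosomes were taken up because of their shift in these same data, and a shifted quartile largely follows from a shifted median, so this adds little. The quartile nearer to 0 was also shifted by 0.22 on chromosomes 5 and 18, and the 75th percentile by -0.26 on chromosome 4 and -0.22 on chromosome 3, so smaller shifts of this kind, past the 0.2 asked of this test, are not special to chromosomes 1 and 11; 3 copies in place of 2 would give 0.58, and a loss of chromosome 11 from the null culture or of chromosome 1 from the heterozygote culture would look alike here.

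A further pattern is the set of genes nearly absent from 1 library. A minority of other cells mixed into a heterozygote culture otherwise like the null culture would dilute null-type transcripts only by its share. Of 5495 genes with an FPKM of at least 20 in the null library, 359 (6.53%) lay under 50% of that value in the heterozygote library and 42 under 10%, which such a minority cannot give; this follows from the counts of changed genes already seen and is no independent test, and it leaves open cultures that differ in other ways as well. For the mesothelial genes themselves, 92.3% of expressed members were at least 2-fold higher in the heterozygote library. A share of mesothelial cells, small or large, that passed the sort cannot be told apart from a mesothelial state of the cultured cells. A bulk value does not separate them. The 2 cultures came from different mice, as the genotypes and the sex-linked transcripts show. A difference between these mice or their tumours may also contribute and stays untested, as does an effect of genotype.

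The list of unfolded protein and amino acid stress genes had a median of 1.27, while the central 95% of random lists of the same size and expression spanned -0.30 to 0.13. A factor for a whole library moves such genes nearly alike, so scaling does not set this list apart from them; this comparison was chosen after the values were seen, in place of the 3 scalings planned, which move all genes together and decide nothing. The median was 1.28 after centring by GC content and transcript length, which argues against such bias as the whole cause of the shift of this list, although 8 of its 20 members, among them Chac1, Phgdh and Sesn2, lay within 2-fold. The hypothesis that loss of Cd248 raises this programme is open, since culture conditions on the day of harvest, sex and chromosome content were not separated from genotype by 1 library each.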
